A study of Arabidopsis thaliana with 24 samples.

How the data were processed

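Arabidopsis thaliana plants that lack AP1 and CAL and carry a fusion of AP1 with the steroid-binding part of the glucocorticoid receptor (AP1-GR) make masses of inflorescence-like meristems. Dexamethasone activates the fusion protein, after which flowers start to form at about the same time. Tissue rich in such meristems and young flowers was taken on days 0, 1, 2, 3, 4 and 5 after activation with 1 µM dexamethasone, from about 25 plants per time point, in 4 biologically independent sets, per the labels. Decapped mRNA (transcripts without the 5′ cap, isolated from polyadenylated RNA by an adaptor-based method derived from RLM-RACE) and total polyadenylated mRNA of each sample were amplified from a poly(A) primer, labelled with different dyes and put together on 1 long-oligonucleotide array, per the labels' protocols. Each day thus had 4 arrays, of which 2 carried decapped mRNA in Cy3 and 2 in Cy5, and the series held 24 arrays.

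The deposited table held 26102 probes on 24 arrays, with values from -10.53 to 10.07, read here as log2 ratios of the 2 channels that the authors had normalized. Background correction and normalization are not given in the sources used here, nor are the log base and the direction of the ratio. Correlations over all probes were above 0 for every pair of arrays, including pairs of opposite dye orientation, so the table had been turned 1 way before deposit. The direction was taken as decapped over total, which is likely because channel 1 is decapped mRNA on each sample whatever its dye. Also, the only gene that RefSeq calls an rRNA, AT2G01020, had the highest mean ratio. That gene has 1 probe, and much of its spread (SD 2.68) went with dye orientation (SE 0.348 after a dye term). It lay above 0 on all 24 arrays. If the table holds total over decapped, each "higher" below reads "lower". Log base 2 is likely from the range of the values. Scale and direction thus stay unknown, and so does the authors' centring.

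The medians of the array columns over all probes, in order of sets 1 to 4, were -0.14, 0.04, -0.04 and -0.04 on day 0, and 0.14, -0.12, 0.04 and 0.03 on day 1. They were -0.02, -0.02, 0.02 and -0.04 on day 2, and 0.30, -0.14, -0.04 and 0.03 on day 3. On day 4 they were -0.07, -0.04, -0.03 and -0.03, and on day 5 they were 0.03, -0.03, 0.03 and 0.03. On each day between 770 and 4424 probes held 1 shared value on all 4 arrays, of equal size and of opposite sign for the 2 dye orientations. Such values were read as no measurement, a choice made from their form before any test was run. Only this most common set of 4 values of each day was removed. Between 3831 and 5397 probes a day, these included, shared their 4 values with another probe, and the rest were kept. The table has no empty cells, and no other mark of dim spots was given, so how far signals stood above background is unknown. For arrays, precision is limited by their number.

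The platform annotation paired 13960 probes with 1 gene and 0 with several, and 12142 probes stayed unnamed. Of the named probes, 13912 matched a gene of the RefSeq table for the TAIR10.1 assembly and 48 did not. That table gave symbols, the kind of gene and the gene span only. The annotation's build is not named, so positions are not given. Probes of 1 gene were averaged, and a gene needed at least 2 values on each day. Of 13745 genes, 3138 were left out because a day held only the shared value, and 10607 were tested, each with values on 24 arrays, 203 of them from more than 1 probe. All 24 sample columns were used and 0 were left out.

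Ratios were fitted per gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a mean for each day and a term for the dye orientation, over all 24 arrays. Two-sided tests with Benjamini-Hochberg adjustment at a threshold of 0.05 covered the mean of the 6 day means against 0, each day mean against 0, days 1 to 5 against day 0, a moderated F test over days and a slope per day. Camera, limma's competitive test of a gene set, was run with its preset correlation of 0.01 on the 9 of 15 fixed lists that had at least 3 measured members, with adjustment over those 9. Lists of photosynthesis, histone and ribosomal protein genes and of transcription factor families were matched by symbols or their synonyms. Only 1261 of the 10607 tested genes had a symbol other than their locus, so such lists can miss measured members. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The scripts were tested on simulated data with 200 changed genes among the 10607. The simulated noise was independent between arrays, with no link within sets and no dye effect. The shares recovered may therefore not hold for the real arrays. A mean shift of 0.5 was recovered in 33.5% of changed genes, of 1 in 92% and of 2 in 99.5%. Day 5 minus day 0 differences of 1, 2 and 3 were recovered in 0%, 59% and 84.5%, changes of 1, 2 and 3 on 1 day by the F test in 0%, 53.5% and 83%, and slopes with a total change of 1, 2 and 3 in 5.5%, 65.5% and 89.5%.

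Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 10 highest and 10 lowest means among genes past the threshold with 1 sign on all 24 arrays and a symbol other than their locus. For changes over days it took the 10 largest rises and falls from day 0 to day 5 among genes past the F test with no overlap of the arrays of both days. Up to 2 members per direction of each list were added by the smallest p, and 13 regulators of flowers and RNA decay always, of which only VCS was measured. The design text describes each set as sampled on all 6 days, so set numbers pair the arrays across days. Deviations of arrays from their day means, across genes, correlated with a median of 0.28 between days within a set (from -0.19 to 0.70, 48 of 60 pairs above 0.1) against -0.09 between arrays that differ in both set and day. Within a set the median was 0.32 for opposite and 0.19 for equal dye orientation. The best match on another day had the same set number for 22 of 24 arrays. The 24 arrays are therefore not fully independent, and the value with set number as a block is given where it changes a call. For the mean of all days a fixed block takes the differences between sets out of the error, so it is not a stricter test. Set as a random block and set means count those differences as error.

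Alternatives were centring each array, centring and scaling, no dye term, set as a fixed block, separate probes, robust empirical Bayes, array weights, a threshold of 0.01, fits on only the days compared, and leaving out each array or set. For lists they were an estimated correlation and fry, which tests whether a set's genes move, on balance, 1 way. Chosen after the data were seen were a list of 75 ribosomal protein loci, 36 families of at least 5 genes sharing a symbol stem, shared values kept, all shared sets of 4 values removed, set as a random block, set means, removal of the gene span trend, and removal of the 3 arrays that correlated least with the rest. Those 3 arrays were set 1 on days 1, 2 and 3.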

Results

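Decapped and total mRNA were compared on 24 arrays, 4 on each of days 0, 1, 2, 3, 4 and 5 after activation of AP1-GR, a steroid-inducible form of the floral regulator AP1. Decapped transcripts are intermediates of 5′ to 3′ decay or products of cleavage, so a high ratio marks a transcript that was richer in the decapped pool than in the total pool of the same tissue. All values are log ratios, likely log2 and likely decapped over total. They were available for 10607 genes after filtering. The number of arrays limits the precision, with a median 95% interval of ±0.30 for the mean of all days, ±0.72 for 1 day and ±1.02 for a difference from day 0. These intervals take the 24 arrays as independent. Arrays of a set were linked across days (correlation 0.165 with set as a random block), so the interval for the mean is likely too narrow.

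The first comparison asked which transcripts were richer or poorer in the decapped pool over all 6 days. Of 7 measured genes for light harvesting and the photosystems, found by symbol or synonym, 6 were lower (camera adjusted p = 0.00833, 0.186 with an estimated correlation). The histone genes HTB1 and HIS4 were also lower, while POL and UBP21 were among the genes with high ratios on all arrays. HTB1, a histone H2B gene, had a mean ratio of -2.95 ± 0.57 (SD, n = 24) and LHCB4.2, a light-harvesting protein gene, had -2.70 ± 0.54. POL, a protein phosphatase gene that acts in meristem maintenance, stood at 2.17 ± 0.70 and UBP21, a ubiquitin-specific protease gene, at 2.10 ± 0.48. In total 3148 genes (29.68%) were higher and 4611 (43.47%) lower by limma, with the 24 arrays taken as independent. Of these, 2236 and 3709 were also called from set means (n = 4). Counted without a test, 767 genes lay above 0 and 1312 below 0 on all 24 arrays.

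The low side reached further than the high side. Ratios of at least 2 below 0 were called for 755 genes and at least 2 above 0 for 57, and at least 1 for 2518 and 1041. The median of all tested genes was -0.16. Centring each array on its median moved all genes up by 0.16 and brought the share of higher among called genes from 40.6% to 49.3%. Relative to the median gene, named ratios below read 0.16 higher.

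Among genes with a symbol and a ratio above 0 on all 24 arrays, the 10 highest were SBT1.3 (2.35 ± 1.26), POL, UBP21, TRM19 (2.09 ± 0.78), CTF2A (2.08 ± 1.12), PSY1R (2.08 ± 0.96), SBT3.5 (2.02 ± 0.95), CSLC6 (1.99 ± 0.48), CFM3B (1.94 ± 0.94) and RXW8 (1.93 ± 0.52). SBT1.3 and SBT3.5 encode subtilisin-like proteases, PSY1R a receptor kinase for a sulfated peptide, TRM19 a protein with a TON1-recruiting motif and CSLC6 a cellulose synthase-like protein. Their adjusted p-values ran from 7.11e-13 for UBP21 to 9.5e-08 for CTF2A. The largest mean of all was that of AT2G01020, annotated as an rRNA, at 5.54 ± 2.68 and above 0 on 24 of 24 arrays (adjusted p = 1.45e-11).

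Among genes with a symbol and a ratio below 0 on all 24 arrays, the 10 lowest were MOB1-like (-4.00 ± 1.46), IMP4 (-3.63 ± 1.58), NdhN (-3.56 ± 1.72), SNF7.1 (-3.47 ± 0.96), CDI (-3.45 ± 1.47), BOB1 (-3.42 ± 0.98), ILR3 (-3.36 ± 0.72), ATARD2 (-3.22 ± 0.85), NRPB6A (-3.22 ± 1.11) and AVA-P1 (-3.14 ± 0.67). IMP4 encodes a component of the machinery that processes ribosomal RNA, and NRPB6A a subunit of nuclear RNA polymerases. SNF7.1 encodes a subunit of the ESCRT-III complex, AVA-P1 a proteolipid subunit of the vacuolar proton pump, NdhN a subunit of the chloroplast NAD(P)H dehydrogenase complex and ILR3 a helix-loop-helix transcription factor. Each was below 0 on 24 of 24 arrays, with adjusted p-values from 3.2e-14 for AVA-P1 to 1.22e-08 for NdhN.

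**Figure D1:**
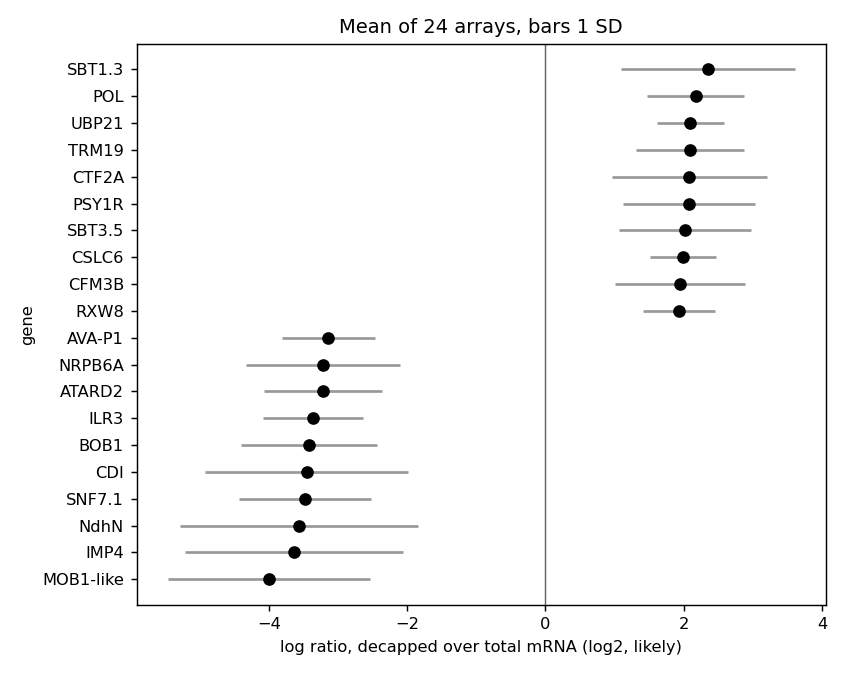
Mean log ratio of decapped over total mRNA (likely log2, horizontal axis) for the 10 highest and 10 lowest genes with a symbol and with 1 sign on all 24 arrays; points are means of 24 arrays and bars 1 SD. The high genes lie between 1.93 and 2.35 and the low genes between -4.00 and -3.14.

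A limit applies to each value of a single gene. Of 150 genes with at least 2 probes measured on their own, 87 had probes on both sides of 0, the probes differed by a median of 1.47, and the first 2 probes did not correlate across genes (r = -0.09, permutation p = 0.297, 10000 shuffles; genes are not independent replicates), so a gene's value belongs to its probe.

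Longer genes had higher ratios. In 5 classes of about equal size by gene span, with median spans of 1014, 1669, 2181, 2855 and 4190 bp, the median ratio was -0.21, -0.38, -0.33, -0.10 and 0.17. In the class of longest span 44.3% of genes were higher, against 21.3% in that of shortest span.

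**Figure D2:**
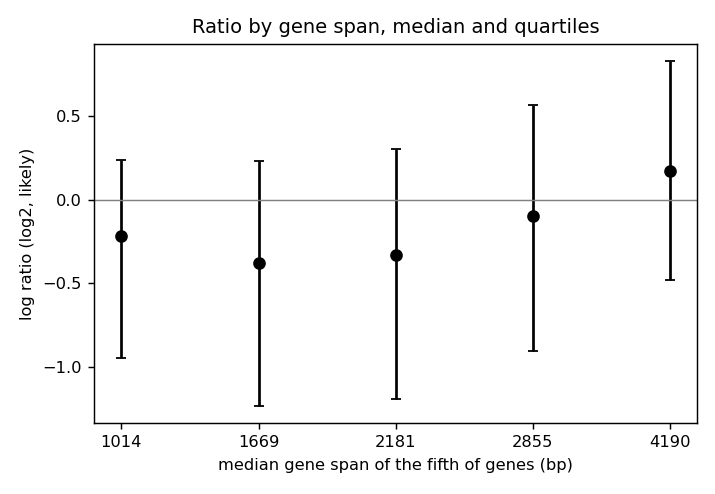
Log ratio (likely log2, vertical axis) by class of gene span, labelled by the median span in bp (horizontal axis), over 10576 genes; points are medians and bars quartiles. The median is highest, at 0.17, in the class of longest span.

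Photosynthesis proteins encoded in the nucleus were the only fixed list that camera placed apart from other genes. Of 7 measured members 6 were lower and 0 higher, with a median of -2.01 (camera adjusted p = 0.00833 over 9 lists; adjusted p = 0.186 with an estimated correlation). Adjusted over the list alone, 7 were lower. PSBY (-2.94 ± 1.51), LHCB4.2 and PSAN (-2.22 ± 0.64), parts of the photosystems and their antenna, were below 0 on all arrays. PSAE-1, a photosystem I subunit, was at -0.38 ± 0.99 and did not pass over all genes, but passed with set number as a fixed block (adjusted p = 0.0462, limma). It did not pass with set as a random block (0.171), from set means (0.123) or with centring (0.285). It did pass with array weights (-0.425, adjusted p = 0.0112, limma). The same held without some single arrays, such as set 3 of day 1 (0.0146) and set 2 of day 2 (0.0395).

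Regulators of flowers went both ways. Of 7 measured floral genes, UFO (1.01 ± 0.30), an F-box cofactor of LFY, and SPT (1.12 ± 0.48), a carpel regulator, were higher. RBE (-0.43 ± 0.49), a petal regulator, KNU (-0.31 ± 0.63) and SPL (the sporocyte gene SPOROCYTELESS, -0.33 ± 0.69) were lower, while JAG at 0.13 ± 0.67 and PTL at -0.05 ± 0.40 did not pass. Adjusted over the list alone the counts were also 2 higher and 3 lower. The list's median was -0.05 (0.11 with centring), its mean 0.16 and camera's direction up (adjusted p = 0.545), so the signs differ. SPL and KNU lost their calls when each array was centred (-0.17 and -0.15, adjusted p = 0.225 and 0.296), and from set means (n = 4) 0 floral genes were lower.

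Among 5 inflorescence and flowering-time genes, SMZ (0.81 ± 1.15) and FD (0.24 ± 0.44) were higher and AGL24, a promoter of inflorescence fate, was lower at -0.84 ± 0.43. FD did not pass without 1 array for 18 of the 24 arrays, nor from set means (adjusted p = 0.243, limma). SNZ and AGL42 did not pass, at -0.14 ± 0.61 and -0.01 ± 0.47. Over the list alone 1 was higher and 1 lower, and camera's adjusted p was 0.81; its direction was up, like the mean of 0.01, with a median of -0.01 (0.15 with centring). All 3 measured meristem and boundary genes were lower, namely LOB (-1.31 ± 0.64), LAS (-0.98 ± 1.25) and CLV3 (-0.30 ± 0.51), with a median of -0.98 (camera adjusted p = 0.453), 3 also over the list alone. CLV3, the stem cell peptide gene, lost its call with centring (-0.15, adjusted p = 0.274) and with set as a random block (0.0895). From set means 1 of the 3 genes was lower, and LAS (0.0692) and CLV3 (0.154) did not pass.

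Targets of microRNAs and of trans-acting small RNAs, whose slicing leaves an uncapped 3′ part, had 6 measured members of 78. APS3 (1.86 ± 0.47), an ATP sulfurylase gene, PHV (1.13 ± 0.88), a regulator of organ polarity, and SMZ were higher. APS4, a paralogue of APS3, was lower at -1.25 ± 1.17, and SNZ and AGL16 (-0.07 ± 0.39) did not pass. The median was 0.37 and camera did not separate the list (adjusted p = 0.453), with 3 higher and 1 lower over the list alone.

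In the decay machinery 4 of 6 measured genes were higher. These were VCS (0.64 ± 1.02), a scaffold of the decapping complex, and 3 loci without a symbol in RefSeq, AT2G39260 (0.89 ± 0.55), AT1G79090 (0.59 ± 0.84) and AT3G46960 (1.69 ± 1.14), which the list fixed beforehand holds as UPF2, PAT1 and SKI2. RRP41, a core subunit of the 3′ to 5′ exosome, was lower at -2.02 ± 0.76 and LSM1B was at 0.16 ± 0.33, which did not pass but was higher with centring (0.32, adjusted p = 0.00191). VCS did not pass without set 3 (0.43, adjusted p = 0.0975), without set 4 (0.0640) or from set means (0.0836). The median was 0.62 (camera adjusted p = 0.453), and 4 were higher and 1 lower over the list alone. The 4 higher genes span 4230 to 7889 bp, against 2890 bp for RRP41 and 1887 bp for LSM1B. The higher members are thus the longest of this list. RRP41, however, lies near the median span of 2855 bp of a class whose median ratio was -0.10. Its low value thus does not follow the trend on gene span.

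Among 5 histone genes found by symbol or synonym, HTB1, HIS4 (-1.78 ± 1.01) and HTR12 (-0.36 ± 0.39), the centromeric histone H3 gene, were lower. HTB2 (0.35 ± 1.21) and HTB4 (0.17 ± 1.32), other H2B genes, did not pass. HTB4 did pass as higher with centring (0.33, adjusted p = 0.011) and HTB2 without set 1 (0.48, adjusted p = 0.041), and HTR12 did not pass from set means (0.0734). HTB4 lay above 0 on only 12 of 24 arrays, and most of its spread went with dye orientation (SE 0.108 after the dye term). Its call thus averages arrays of opposite sign. A dye effect passed the threshold in 74 genes by limma. The list's median was -0.36 (camera adjusted p = 0.493), with 0 higher and 3 lower over the list alone. Of 3 Aux/IAA genes, repressors of auxin signalling, IAA29 (0.92 ± 0.83) was higher and IAA18 (-0.85 ± 0.51) and IAA30 (-0.89 ± 0.62) lower (median -0.85, camera adjusted p = 0.81, 1 and 2 over the list alone). The 7 measured genes with an IAA symbol, grouped after the data were seen, had 4 higher and 3 lower and a median of the opposite sign, 0.40 (camera adjusted p = 0.811 over 36 families).

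In 47 members of transcription factor families 8 were higher and 14 lower (7 and 13 over the list alone). BZIP53 (3.04 ± 1.42, above 0 on 23 of 24 arrays) and WRKY20 (1.79 ± 0.49) were the strongest by p on the high side, AGL72 (-1.94 ± 0.76) and AGL26 (-1.89 ± 0.43) on the low side. The list's median was -0.07 and its mean -0.14 while camera's direction was up (adjusted p = 0.81), so the signs differ. The balance depended on the scaling: with centring 17 were higher and 12 lower, with a median of 0.09, and with scaling 15 and 10, with a median of 0.06. AGL58, for example, was then higher (0.62, adjusted p = 0.0156 with centring) and AGL18 did not pass (-0.17, adjusted p = 0.185). Single measured members stood for 3 lists: PRL for cell division (-0.05 ± 0.67, not past), STZ for stress and handling (1.17 ± 1.51, higher) and AT1G77750 for symbols of ribosomal proteins (-0.44 ± 0.42, lower). Markers of other cell types, organelle transcripts and SAUR genes had 0 measured members and were not analysed here.

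**Figure D3:**
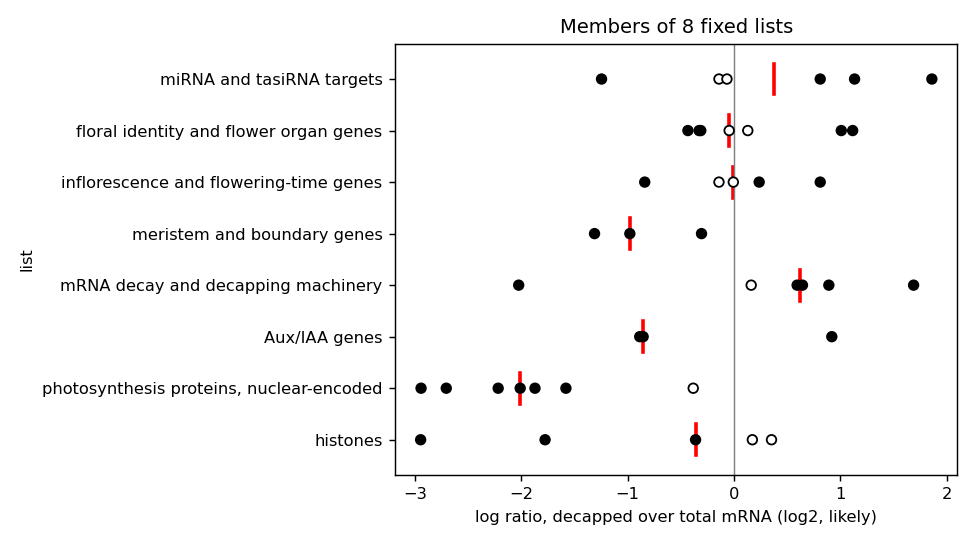
Mean log ratio (likely log2, horizontal axis) of each measured member of 8 lists fixed beforehand; filled points passed the threshold over all genes, open points did not, and red bars are list medians. Photosynthesis genes lie lowest, with a median of -2.01. Centring each array would move all points up by about 0.16, removes the calls of SPL, KNU and CLV3 and adds those of LSM1B and HTB4. HTB4 lay above 0 on 12 of 24 arrays.

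The second comparison took each day on its own. LHCB4.2 was lower on each day, from -2.82 ± 1.05 (SD, n = 4) on day 0 to -2.69 ± 0.37 on day 5, and HTB1 from -3.00 ± 0.19 to -3.04 ± 0.34. UFO was higher on each day, with 1.00 ± 0.22 on day 0 and 1.27 ± 0.52 on day 5, as was SPT, with 0.97 ± 0.48 and 1.03 ± 0.50. RRP41, AGL24 and LOB were lower on each day. VCS passed on no single day, with values from -0.17 ± 0.89 on day 3 to 1.24 ± 0.82 on day 5.

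The same 834 genes were higher and 1542 lower on each of the 6 days, and 3 were higher on 1 day and lower on another. By day, 1235, 1452, 1486, 1301, 1491 and 1938 genes were higher and 2934, 2356, 2090, 2876, 2520 and 2204 lower on days 0 to 5 by limma. Whether these counts differ between days was not tested. They depended on which arrays were used. Without the day's own array of set 2 the higher genes numbered 810 on day 0, 958 on day 1 and 855 on day 2, and the lower genes 1505, 1113, 1649, 1635 and 1428 on days 1 to 5. On day 2 they were 872 higher and 1237 lower without the array of set 3, and 989 higher without that of set 4. Without all arrays of set 4 the higher genes fell to 559 on day 0 and 615 on day 2. Fits on the 4 arrays of 1 day called 224 higher and 1244 lower on day 0 and 0 on days 1, 2 and 3, while days 4 and 5 stayed within 1.5 times their counts. Centring each array raised the higher genes of day 0 to 1891.

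The third comparison asked which transcripts changed their decapped share as flowers formed. The day means of UFO, SPT, AGL24, LOB, RRP41, LHCB4.2 and HTB1 kept 1 sign on all 6 days. These genes were named for a small p in the mean of the same days, which favours 1 sign. The day mean of VCS was below 0 on day 3 alone. None of these 8 genes changed past the threshold. Day 5 minus day 0 was 0.27 ± 0.28 (SE) for UFO, 0.06 ± 0.36 for SPT, -0.04 ± 0.36 for AGL24 and 0.42 ± 0.70 for VCS (limma adjusted p = 0.999 for each). For RRP41 it was 0.16 ± 0.59, for LHCB4.2 0.13 ± 0.40, for LOB -0.04 ± 0.50 and for HTB1 -0.05 ± 0.42. By limma 0 genes passed the F test over days (142 at an unadjusted p under 0.05, 1.34% of genes), 0 each of the 5 differences from day 0 (197, 209, 507, 192 and 330 unadjusted on days 1 to 5) and 0 the slope (234 unadjusted). The 1.34% lies below the share of 0.05 that independent arrays with no day effect would give. A median of 23.6% of the spread among arrays lay between sets (13% with no set effect). Between days it was 13.5% (21.7% with no day effect). The main fit leaves differences between sets in its error, so the lack of calls does not show unchanged ratios. With set number as a block 286 genes had an unadjusted F test p under 0.05.

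With set number as a block, 2 genes rose and 2 fell from day 0 to day 3 and 1 rose to day 5, named here after their values were seen. UGT84A3, a glycosyltransferase gene, fell from 0.46 ± 0.35 (SD, n = 4) to -1.58 ± 0.78 (blocked adjusted p = 0.0401, limma; 0.0895 without the block). AT1G18550 fell from 0.20 ± 0.53 to -1.85 ± 0.60, AT5G37220 rose from -1.45 ± 0.20 to 0.43 ± 0.38, and AT5G09710 rose from -1.58 ± 0.39 to 0.07 ± 0.42 on day 3 and 0.15 ± 0.52 on day 5. UGT84A3 also passed on day 3 when each array was centred (adjusted p = 0.0207). Leaving out set 1 gave 106 lower and 5 higher genes on day 3, and 0 and 0 once arrays were also centred and scaled.

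No list had a trend over days by camera (adjusted p = 0.908 for each of the 9), and 0 members of any fixed list passed for the slope. The member with the smallest slope p among transcription factor families was AGL102, a MADS-box gene, with -2.93 on day 0 and -0.33 on day 5 (unadjusted p = 0.0339), and among floral genes JAG, with 0.62 and 0.13 (unadjusted p = 0.127). Day means correlated across genes between 0.86 and 0.94. In simulated data with independent arrays, day 5 minus day 0 differences of 1 were recovered in 0% of changed genes and of 2 in 59%. Slopes with a total change of 1 were recovered in 5.5%.

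**Figure D4:**
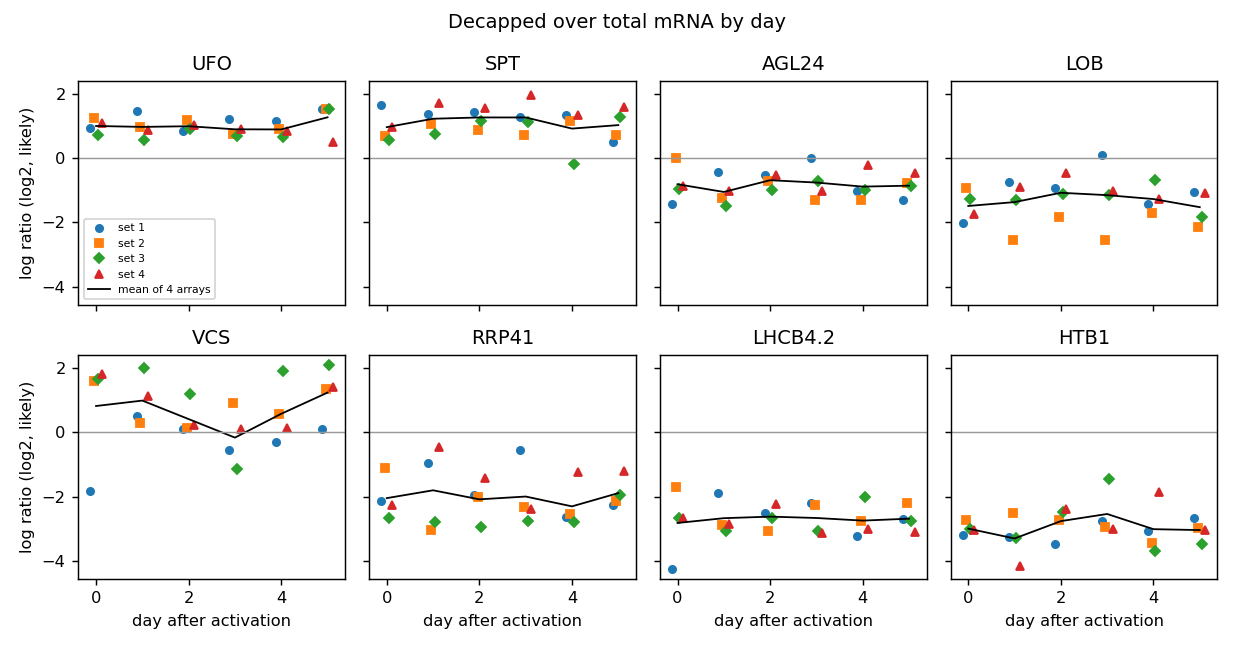
Log ratio (likely log2, vertical axis) of 8 genes by day after activation (horizontal axis); symbols are single arrays of sets 1 to 4 and lines the means of 4 arrays. UFO and SPT stay above 0 in the mean on each day and LHCB4.2 and HTB1 stay below -2 in the mean, while VCS spreads from -1.83 to 2.09.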

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

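Tests chosen only after the result was seen were those of gene span, the splits of the sets by sign, and the counts of regroupings for the F test, the slope and each day. The exchange of set 1 between days 0 and 3 was the split with the most genes among 35 for day 3. Its tests thus concern a pattern found in these same data.

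UFO, SPT, VCS, RRP41 and HTB1 each had an array that stood apart from the other 3 of its day. UFO was at 0.50 in set 4 on day 5, against 1.52 to 1.54 in the other sets, and SPT at -0.18 in set 3 on day 4, against 1.17 to 1.36. VCS was at -1.83 in set 1 on day 0 (others 1.61 to 1.82) and at 1.18 in set 3 on day 2 (others 0.10 to 0.24). RRP41 was at -1.25 in set 4 on day 4 (others -2.81 to -2.54), and HTB1 at -1.45 in set 3 on day 3 (others -3.02 to -2.77). These were 6 of 60 groups of 4 arrays tested, and chance gives about 1 in 20.

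Probes that the annotation does not pair with a gene were not used in the comparisons of the report. Of 9473 such probes measured on all days, 3426 (36.2%) were higher and 3449 (36.4%) lower in the mean of all days by limma, with a median of 0.01. All 24 arrays lay above 0 for 835 and below 0 for 908 of them.

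Probes of the same gene gave unrelated ratios in the 150 genes with at least 2 measured probes. Noise between arrays is argued against, since the first 2 probes differed in 83.3% of these genes (limma, adjusted p under 0.05). A wrong pairing of probes with genes stays open for these genes. Deviations of both probes from their day means had a median correlation of 0.124, within the range of 0.004 to 0.148 of random pairs. The place of a probe in its transcript may also matter and was not tested, because probe sequences were not used here, and no biological explanation was tested.

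The ratio was higher in genes of longer span, which groups UBP genes with long genes and ribosomal protein genes with short ones. Across 10576 genes Spearman's correlation was 0.178, from -0.015 to 0.409 on single arrays and above 0 on 23 of 24 (genes are not independent replicates). A loss of long cDNA from the decapped preparation stays open because the direction of the ratio is not given: it would lower the ratio of long genes if this is decapped over total, and raise it if it is total over decapped. Span as the whole cause is argued against for ribosomal protein genes. Their median of -2.13 lay below the -0.824 to 0.021 of sets matched on span. Span is that of the gene, so a cause in transcript length is not covered and was not tested. For 12 UBP genes span as the whole cause cannot be told apart. Their median of 0.81 lay above the -0.534 to 0.79 of matched sets by less than its standard error of 0.204. Another property that goes with span may be the source, and no biological explanation was tested.

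For changes over days 0 genes passed by limma (142 at an unadjusted p under 0.05 by the F test), yet 626 passed on day 3 when the set 1 arrays of days 0 and 3 were exchanged. A day effect over many genes, hidden by the differences between sets, was not seen with the day labels as given. With set number as a block 286 genes had an unadjusted p under 0.05 by the F test. Permutations of days within sets gave a median of 377 and up to 1335. Their days were not kept balanced over the dyes, and the power of this count was not tested. Such an effect thus stays open. Single genes did pass, as with that block 2 genes rose and 2 fell from day 0 to day 3. Unequal spread of the arrays stays open, as 2 genes passed after the exchange once arrays were centred and scaled. Exchanged labels also stay open, since both arrays correlated more with the other day, by at least 0.068, though 7 of 60 exchanges of a set between days gave a value above 0 and 2 at least as large. Each array carries the shared value of its own day, which argues against an exchange after that step, and a biological difference between sets is untested.

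For the mean of all days the real signs gave 7759 genes. Of 100 draws of signs per array 1, the real one, gave as many and the highest other gave 4950, but these draws ignore that arrays of a set are paired. With signs per set, 1 of 8 splits, the real one, gave as many and the highest other gave 4310, and 8 splits are too few for a share under 0.05.

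For changes over days the real count was 0, so the regroupings could only give as many or more and decide nothing: 100 of 100 draws for the F test (highest other 10), 100 of 100 for the slope (140), and 35 of 35 splits for each of days 1 to 5 (45, 1, 626, 1 and 1). They were made without the set block. The 626 genes of the split on day 3 are those of the exchange of set 1 above and point to a structure of the samples, for which unequal spread and exchanged labels both stay open.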

How the results depend on the processing

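Chosen only after the result was seen were the tests with set as a random block, set means, shared values kept, all shared sets of 4 values removed, and removal of 3 arrays. Counts for the mean of all days stayed within 1.5 times under each alternative on genes. The same 3142 higher and 4602 lower genes were called with set number as a block, 2593 and 4103 with it as a random block, and 2236 and 3709 from set means (n = 4). No named gene, list or family that passed in the main fit changed sign under an alternative. Some balances of counts did turn. In transcription factor families 8 higher and 14 lower became 17 and 12 with centring. On day 5, 1938 higher and 2204 lower became 4064 and 3737 with separate probes, where the unit differs. Of the other results for single genes and families under the alternatives, 6151 kept their side of the threshold, 86 lost a call and 46 gained one. These include slopes of single genes, of which none had passed, so that they could only keep their side or gain a call. The cause of changes under an alternative was not tested except where fewer arrays or a stricter threshold explain a lower count.

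With centring, higher genes on day 0 numbered 1891 and 1 gene was lower on day 3 than on day 0, as with scaling (1). The replicate block gave 2 higher and 2 lower genes on day 3 against day 0 and 1 higher on day 5, and the random block (correlation 0.165) gave 3, 2 and 1. Array weights gave 3264 lower genes on day 2, and 1, 4 and 1 higher for day 4, day 5 and the slope, among them SERPIN1 and PDF1.3. Without the 3 least correlated arrays 1 gene was lower on day 3 than on day 0. Separate probes (20231, of which 9473 have no gene and are not among the tested genes, so that both the unit and the set of features differ) gave 6639 higher and 8127 lower in the mean, and 2714 and 5044, 3050 and 3922, 3172 and 3590, 2736 and 4947, 3166 and 4277, and 4064 and 3737 on days 0 to 5.

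At a threshold of 0.01, day 0 had 686 higher genes, and days 1 to 5 had 862 and 1544, 846 and 1132, 761 and 1862, 918 and 1576, and 1154 and 1346 higher and lower. Fits on 1 day's arrays gave 224 and 1244 on day 0, and 0 and 0 on each of days 1, 2 and 3.

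Leaving out 1 array or 1 set gave 2561 to 3266 higher and 3898 to 4712 lower in the mean. Days 0 to 5 gave 559 to 1526, 786 to 1627, 615 to 1938, 682 to 1404, 661 to 1677 and 1142 to 2105 higher, and 1749 to 3084, 1228 to 3033, 952 to 2839, 1443 to 3644, 1372 to 2922 and 1229 to 2493 lower. Day 3 against day 0 gave 0 to 5 higher and 0 to 106 lower (both highest without set 1), day 5 gave 0 to 1 higher, and the F test 0 to 1, AT1G09040 without set 2 (adjusted p = 0.025).

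Photosynthesis genes lost camera's call with an estimated correlation (adjusted p = 0.186, range 0.00379 to 0.186 over 10 alternatives of camera). Fry, which compares no set with other genes, called microRNA targets (1.94e-09), floral (8.09e-04) and decay (0.00208) genes up. It called photosynthesis (2.57e-13), meristem (1.68e-06), Aux/IAA (1.95e-04), histone (2.52e-09) and transcription factor (0.00434) genes down. For transcription factors camera's direction was up, and with centring 17 were higher and 12 lower. Leaving out set 2 ended the calls of SPL (-0.16, adjusted p = 0.29), LAS (0.0695), CLV3, FD, AGL95 and BZIP24. Without set 3 those of SPL, FD and VCS (0.0975) ended and PSAE-1 passed (0.0199). Without set 4 those of FD, LAS (0.0568), VCS (0.064), AGL95 and BZIP24 ended, and without set 1 that of CLV3 ended and HTB2 passed (0.041). SPL and CLV3 lost their calls with centring, scaling, a random block and set means, and FD with the latter pair (adjusted p = 0.141 and 0.243) and without 1 array for 18 of 24 arrays. Set means also ended the calls of VCS (0.0836), RBE (0.0631), LAS (0.0692), HTR12 (0.0734), AGL95 (0.11) and BZIP24 (0.0624), leaving 0 floral and 1 meristem genes lower. Restriction to genes on all 24 arrays removed no gene. Signal over background is not given in the sources used here.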

Other observations

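Lists and families below, and their tests, were chosen only after the data were seen. Genes for proteins of the cytosolic ribosome, written down by locus, had low ratios. Of 39 measured among 75 loci, 28 were lower and 5 higher, with a median of -2.13 (camera p = 9.21e-05, p = 0.157 with an estimated correlation). AT2G17360 was at -4.70 ± 1.07 (SD, n = 24), AT2G31610 at -4.26 ± 1.60, and AT3G09630 on the other side at 1.39 ± 1.72. Of 12 UBP genes, ubiquitin-specific proteases, 11 were higher and 0 lower by limma, with UBP21 at 2.10 ± 0.48, UBP16 at 1.47 ± 0.48 and UBP19 at 1.33 ± 0.48. Their median was 0.81 (camera adjusted p = 8.42e-04 over 36 families, 0.458 with an estimated correlation), and 0.43 with the trend on gene span removed (adjusted p = 0.0785).

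Other families lay to 1 side without passing camera. All 6 NRPB genes, subunits of RNA polymerase, were lower (median -1.25, adjusted p = 0.0621, 0.0494 without set 3 and 0.372 with an estimated correlation), NRPB3 at -2.23 ± 0.85. Of 7 GLR genes, glutamate receptor-like channels, 6 were higher (median 0.84, adjusted p = 0.0593, 0.372 with an estimated correlation, 0.0426 with set number as a block, 0.0383 without set 1, 0.0494 without set 3, 0.0322 without the 3 least correlated arrays and 0.257 with the trend on gene span removed), GLR1.4 at 1.52 ± 0.79. Of 9 EXPA genes, expansins that loosen cell walls, 8 were lower (adjusted p = 0.118), and of 7 CML genes, calmodulin-like, 6 (median -2.05, adjusted p = 0.105).

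The symbol stem PDF was the only family of 36 with a trend over days by camera on all arrays (adjusted p = 6.72e-04, 0.0668 with an estimated correlation, and 0.0852 by fry). On fewer arrays CHX (0.0404 without set 3, 0.0048 without the 3 least correlated arrays), SWEET (0.0404 without set 3) and NET (0.0481 without set 2) also passed. Its 4 plant defensin genes had means nearer 0 on day 5 than on day 0: PDF1.3 went from -1.82 ± 0.42 (SD, n = 4) to -0.17 ± 0.35, PDF1.2 from -1.72 to -0.47, PDF1.2c from -2.43 to -0.47 and PDF1.2b from -2.14 to -0.17. By limma 0 of 6 members passed for the slope over all genes (234 genes at an unadjusted p under 0.05) and 3 adjusted over the family alone. PDF1A and PDF1B, peptide deformylases that share the stem, differed by 0.03 and 0.07. Whether near-identical defensin transcripts share probes was not tested.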
